A study of Mus musculus with 13 samples.

How the data were processed

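Expression was measured in whole brain hemispheres of mice on Affymetrix MG-U74Av2 arrays, on which each gene is read by 1 or more sets of short probes. The 13 arrays were grouped by genotype and treatment as their titles give them. There were 3 wild type untreated arrays, 3 wild type arrays with the triple treatment, 4 untreated R6/2 arrays and 3 R6/2 arrays with the triple treatment. The R6/2 mouse carries the first exon of the human huntingtin gene with a long CAG repeat and is a model of Huntington's disease. The triple treatment combined tacrine (2.7 mg/kg per day), moclobemide (10 mg/kg per day) and creatine (1% in the mash), with tacrine from 5 weeks of age. The descriptions list the drugs for every sample, the untreated ones included, so treatment was taken from the titles alone. A harvest age of 8 weeks is stated for 1 wild type untreated sample only. The labels give no sex, batch or pairing, and they do not say whether each array is a separate animal, so every p-value measures the spread between these samples.

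The deposited values are intensities on a linear scale, scaled by the authors so that the mean of each array after trimming 2% at each end is about 100 (100.047 to 100.128). The labels do not name the software that made them. The median of the gene probe sets was 39.6 to 45.1 per array, and no array lay more than 6.73% from the mean of these medians. By a rule fixed before the data were examined, medians within 10% of their mean meant that the values were used without further normalization. Values under 3.1, the 10th percentile of all values, were set to 3.1, and log2 was taken. Of 12488 probe sets, 66 controls were left out of the tests. Of the remaining 12422, the 7453 whose mean log2 lay at or above the 40th percentile (a signal of 24.9) were kept. Probe sets were paired with genes through the array's annotation table, in which 10833 had 1 gene, 396 had several and 1193 had none. The kept probe sets covered 5676 genes. The platform gives no read depth, and the number of arrays limits the precision.

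A mean per group was fitted with limma 3.58.1 in R 4.3.3, with all 13 arrays sharing 1 estimate of the spread and moderated variances that followed the intensity. The 7 comparisons were the genotype effect in untreated and in treated mice, the treatment effect in R6/2 and in wild type mice, the interaction of treatment and genotype, and the genotype and treatment effects averaged over the other factor. P-values were adjusted by the Benjamini-Hochberg method over the kept probe sets, with a threshold of 0.05. Simulated data had the same group sizes, with noise drawn independently for each probe set at 1 spread shared by all groups. On these data the fit recovered 82.1% of changes of 1 on the log2 scale in the genotype comparison of untreated mice. It recovered 80.6% in the treatment comparison of R6/2 mice, 71.6% in that of wild type mice and 80.6% in the genotype comparison of treated mice. For changes of 0.5 the shares were 17.9%, 19.4%, 4.48% and 16.4%. At most 5 unchanged probe sets were called in any of these comparisons. In the real data the residual SD was 0.252 to 0.380 in untreated R6/2 arrays and 0.189 to 0.209 in untreated wild type arrays. The shares may therefore be too high for comparisons with the untreated R6/2 group.

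Before the data were examined, 29 lists with 727 genes were fixed. They covered neuron types, transmitter systems, the drug targets, energy metabolism, protein folding and turnover, the circadian clock, glucocorticoid-induced genes, glia, blood, other brain regions and sex-linked genes. Of these genes 509 had a probe set annotated to them alone and 425 were kept, each represented by its brightest probe set. The 28 lists with at least 3 kept genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry.

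The genes named were chosen by a rule fixed before the data were examined. It took, per comparison, the 10 largest rises and 10 largest falls past the threshold whose groups did not overlap. Where fewer than 5 passed in a direction, it took the 5 with the smallest p. It added the 4 members with the smallest p of each list that passed, the targets of the drugs and the genes of creatine metabolism, known striatal genes for the genotype effect, and sex-linked genes. Probe sets with several genes or none were not named. In comparisons of averaged groups, overlap was not considered.

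The share of genotype-changed probe sets moved back by treatment uses the untreated R6/2 arrays on both sides, which by itself gives opposite signs. It was therefore set beside 100 simulations without any effect and beside the 6 ways to use 2 of the untreated R6/2 arrays for the genotype effect and the other 2 for the treatment effect. Each of these 6 splits was also simulated 20 times without any effect, which was added after seeing the data. The alternatives fixed before the data were examined were quantile and cyclic loess normalization, no filter or a stricter one, no floor or the 25th percentile as floor, a variance model without the trend or with robust estimation, array weights, a fit of only the groups compared, each array left out in turn, other list tests and other choices of probe sets. Leaving out untreated R6/2 arrays 2 and 3, and arrays 2 to 4, was added after seeing the data. Single measures per array were compared with exact 2-sided permutation tests. Other splits of the arrays into groups of the same sizes were counted for each comparison.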

Results

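Gene expression was compared across 13 arrays of mouse brain hemispheres from wild type and R6/2 mice, untreated or given tacrine, moclobemide and creatine together. Tacrine inhibits cholinesterases, moclobemide inhibits monoamine oxidase A, and creatine feeds the phosphocreatine energy buffer. The untreated R6/2 group held 4 arrays and the other groups 3 each. Median signal ranged from 39.6 to 45.1.

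The untreated R6/2 arrays were the most varied group. The first principal component took 33.9% of the variance, and untreated R6/2 arrays 3 and 2 scored 45.7 and 25.4 on it, against 4.09 or less in the other 11. The control probe sets of untreated R6/2 arrays 2, 3 and 4 stood at 1.2 times those of R6/2 treated array 1, R6/2 treated array 3 and untreated R6/2 array 1, in 66 of 66 rows at a tolerance of 0.05. The controls therefore gave no separate measure of RNA quality for those arrays. The 18S ribosomal control was 38.6 ± 9.01 (SD, n = 3) in untreated and 92.8 ± 30.9 (SD, n = 3) in treated wild type mice (exact permutation p = 0.1, the smallest that 3 against 3 arrays can give). Xist, the RNA of the inactive X chromosome, was read at 64.1 to 148.5 in all 13 arrays. The probe sets of the Y-linked genes Eif2s3y, Kdm5d and Uty lay below the filter.

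**Figure D1:**
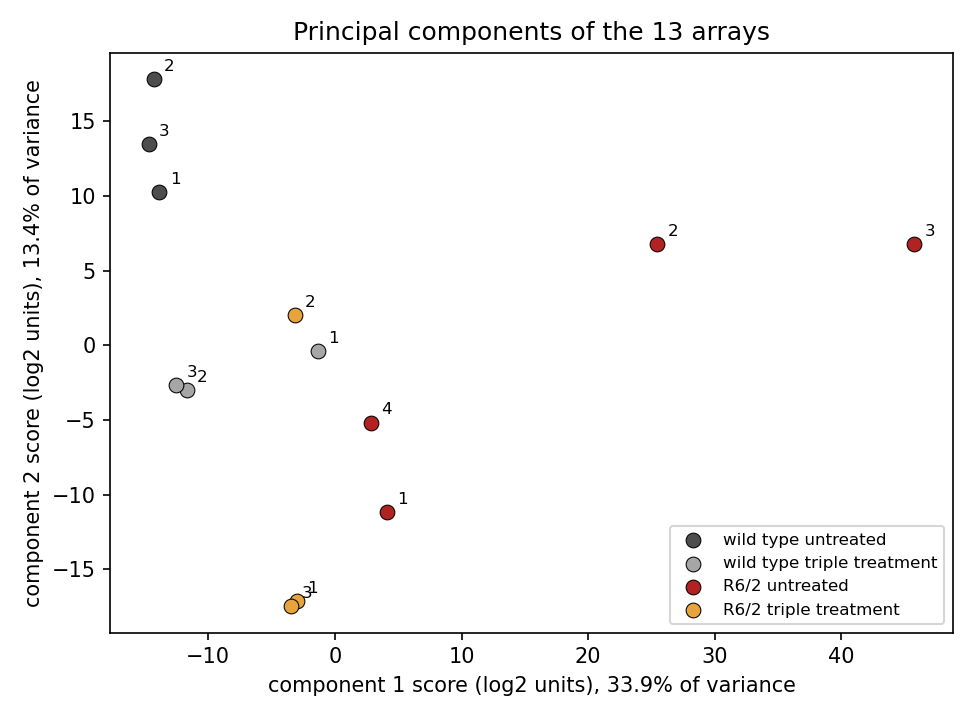
Scores of the 13 arrays on the first and second principal components (log2 units), from the 7453 kept probe sets. Each point is 1 array, coloured by group and numbered by replicate, and untreated R6/2 arrays 2 and 3 lie at 25.4 and 45.7 on the first component.

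The first question was what the R6/2 genotype changed in untreated brain. Genes of striatal projection neurons, the cells most affected in Huntington's disease, were lower in R6/2 mice. Penk, the precursor of enkephalin, had a signal of 1847 ± 105 (SD, n = 3) in wild type and 804 ± 167 (SD, n = 4) in R6/2 mice, a log2 change of -1.22 ± 0.14 (SE, adjusted p = 0.000256). Drd2, the D2 dopamine receptor, changed by -0.76 ± 0.17 (SE, adjusted p = 0.0142), and Pde1b, a calcium-dependent phosphodiesterase, by -1.05 ± 0.17. Hpca, the calcium sensor hippocalcin, changed by -0.84 ± 0.12, and Arpp19 by -1.56 ± 0.18 on the probe set named and by -0.21 on its other probe set. In this list 6 of 12 genes fell, none rose and 6 did not pass (adjusted p of the list = 1.71e-07, 7 falls adjusted over the list alone). For Ppp1r1b, Drd1, Adora2a and Pde10a the annotation gave no probe set with that gene alone, and Cnr1 and Rgs9 lay below the filter.

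Activity-regulated early genes, which neurons switch on when they fire, were lower as well. Of 17 genes, 10 fell and none rose (adjusted p of the list = 1.55e-07, 11 falls adjusted over the list alone). Egr2 changed by -1.97 ± 0.19 (SE, adjusted p = 0.000125), Nr4a1 by -1.18 ± 0.15 and Egr1 by -1.02 ± 0.14, from 625 ± 64.6 (SD, n = 3) to 309 ± 34.7 (SD, n = 4). The phosphatase gene Dusp6 changed by -0.87 ± 0.15. Junb changed by -2.58 ± 0.34 on 1 probe set and by -0.18 on the other. Bdnf, a neuronal growth factor, was at 0.13 ± 0.20 and did not pass (adjusted p = 0.699).

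In the circadian clock list 7 of 16 genes fell and none rose (adjusted p = 0.000394). Bhlhe40, a repressor within the clock, had the smallest p-value of the comparison and went from 255 ± 22.1 (SD, n = 3) to 83.3 ± 10.2 (SD, n = 4), a log2 change of -1.62 ± 0.14 (SE, adjusted p = 6.45e-05). Per1 changed by -1.55 ± 0.17 and the output gene Dbp by -1.21 ± 0.20. In the neuropeptide list 6 of 17 genes fell and none rose (adjusted p = 0.000854). Somatostatin (Sst) changed by -1.68 ± 0.19, its receptor Sstr2 by -1.34 ± 0.27 and cholecystokinin (Cck) by -0.73 ± 0.13.

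Synaptic and signalling genes followed. In the glutamate and GABA list 8 of 21 genes fell (adjusted p = 5.93e-05), among them the GABA receptor subunit Gabrd (-2.12 ± 0.43), the AMPA receptor subunit Gria3 (-1.19 ± 0.25) and the scaffold Dlg4 (-0.85 ± 0.20). Grik5 changed by -1.10 ± 0.23 on 1 probe set and by 0.68 on its other. In the calcium list 6 of 26 fell and 1 rose (adjusted p = 0.000155), with Camk2a at -2.91 ± 0.54 and, on its other probe set, -3.03. Atp2b2, a calcium pump, changed by -1.65 ± 0.26 and Calm2, a calmodulin gene, by 0.75 ± 0.17. In the pan-neuronal list 5 of 17 fell (adjusted p = 0.000155), among them the synaptic vesicle genes Syp (-1.29 ± 0.21) and Syn2 (-0.91 ± 0.14), and Stx1a (-1.17 ± 0.20). This list did not pass with an estimated correlation (adjusted p = 0.0802). Untreated R6/2 arrays 2 and 3 carried much of some of these falls: without them Camk2a was at -1.71, Gria3 at -0.77, Grik5 at -0.62 and Dlg4 at -0.45, and Gria3 and Dlg4 did not pass (adjusted p = 0.0697 and 0.115). In the cortex and hippocampus list 3 of 9 fell (adjusted p = 0.00209), with Wfs1, a gene of the endoplasmic reticulum, at -1.15 ± 0.14.

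In the myelin list 5 of 13 genes fell and all 13 estimates were negative (adjusted p = 1.76e-05, and adjusted p = 0.106 with an estimated correlation). Ugt8a, which makes a myelin lipid, changed by -1.37 ± 0.30 and Mobp by -0.73 ± 0.19, with its 3 other probe sets at -1.2, -1.3 and -1.8. Mag changed by -0.87 ± 0.22 on 1 probe set and by 0.64 on the other. In the sterol synthesis list 2 of 14 fell, Mvd (-1.57 ± 0.43) and Dhcr7 (-0.64 ± 0.16), with an adjusted p of 0.00263 and an adjusted p of 0.0974 with an estimated correlation. In the glucocorticoid-induced list 4 of 13 fell (adjusted p = 0.0168, and adjusted p = 0.106 with an estimated correlation). These were the metallothioneins Mt1 (-1.06 ± 0.15) and Mt2 (-0.58 ± 0.10), the kinase Sgk1 (-0.69 ± 0.13) and Ddit4 (-0.61 ± 0.14). The glycolysis, cholinergic and red blood cell lists were also lower, at adjusted p of 0.0247, 0.0263 and 0.048, and none of them passed with an estimated correlation (adjusted p = 0.308, 0.21 and 0.21). Chrm1, the M1 muscarinic receptor, was the 1 cholinergic gene of 3 that fell (-1.41 ± 0.25). Without untreated R6/2 arrays 2 and 3 the cholinergic and red blood cell lists no longer passed (adjusted p = 0.0525 and 0.137), Chrm1 was at -0.88, and Ddit4 was at -0.40 and did not pass (adjusted p = 0.116).

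Among the largest falls outside the lists were the insulin signalling gene Irs2 (-2.66 ± 0.57), the chaperone gene Dnajb5 (-2.78 ± 0.69, but -1.38 without untreated R6/2 arrays 2 and 3, adjusted p = 0.151), the lipid kinase gene Pip5k1c (-2.33 ± 0.43) and Epop (-2.11 ± 0.35). The largest rises included Rag1 (1.67 ± 0.34), Sfmbt2 (1.53 ± 0.31), the transporter gene Abcb4 (1.22 ± 0.25) and Smc2, a condensin gene (1.2 ± 0.22). Uhmk1 rose by 1.45 ± 0.26 on 1 probe set (0.96 without those arrays), with its others at 0.07 and -1.30, and Akirin1 by 1.41 ± 0.25 with its other at -0.01. The brain creatine kinase gene Ckb changed by -0.72 ± 0.21 (SE, adjusted p = 0.0401), and by -0.36 without those arrays (adjusted p = 0.28). Gamt, of creatine synthesis, was at 0.51 ± 0.14 (adjusted p = 0.0317) and -0.66 on its other probe set. Maoa (0.49 ± 0.17, adjusted p = 0.0707) and Ache (-0.43 ± 0.20, adjusted p = 0.176) did not pass, nor did Ckmt1, Gatm, Slc6a8 or Htt. The mouse Htt probe sets read the mouse gene, not the human transgene. Not all of the largest changes were as clear in treated mice. Rag1 read 69.7 to 97.6 in treated wild type and 42.4 to 103.7 in treated R6/2 mice. Abcb4 read 30.3 to 37.2 and 21.6 to 31.4. Irs2, Pip5k1c, Dnajb5, Smc2, Uhmk1 and Akirin1 also overlapped between the treated genotypes on the probe sets named. Sfmbt2 (11.3 to 18.9 and 33.9 to 47) and Epop did not overlap.

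In all, 887 of 7453 probe sets passed in untreated mice, 409 higher and 478 lower in R6/2 mice, of which 33 and 138 changed at least 2-fold. Of all 7453 probe sets, 1951 (26.2%) had no overlap between the groups, against 5.71% by chance. The count rested in part on single arrays: it was 163 without untreated R6/2 arrays 2 and 3, 73 with untreated R6/2 array 1 alone, and 392, 157 and 220 without wild type untreated arrays 1, 2 and 3 in turn. Without untreated R6/2 arrays 1, 2, 3 and 4 in turn it was 1247, 397, 491 and 1308. It was 243 when only the 7 arrays compared were fitted and 512 without the filter.

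**Figure D2:**
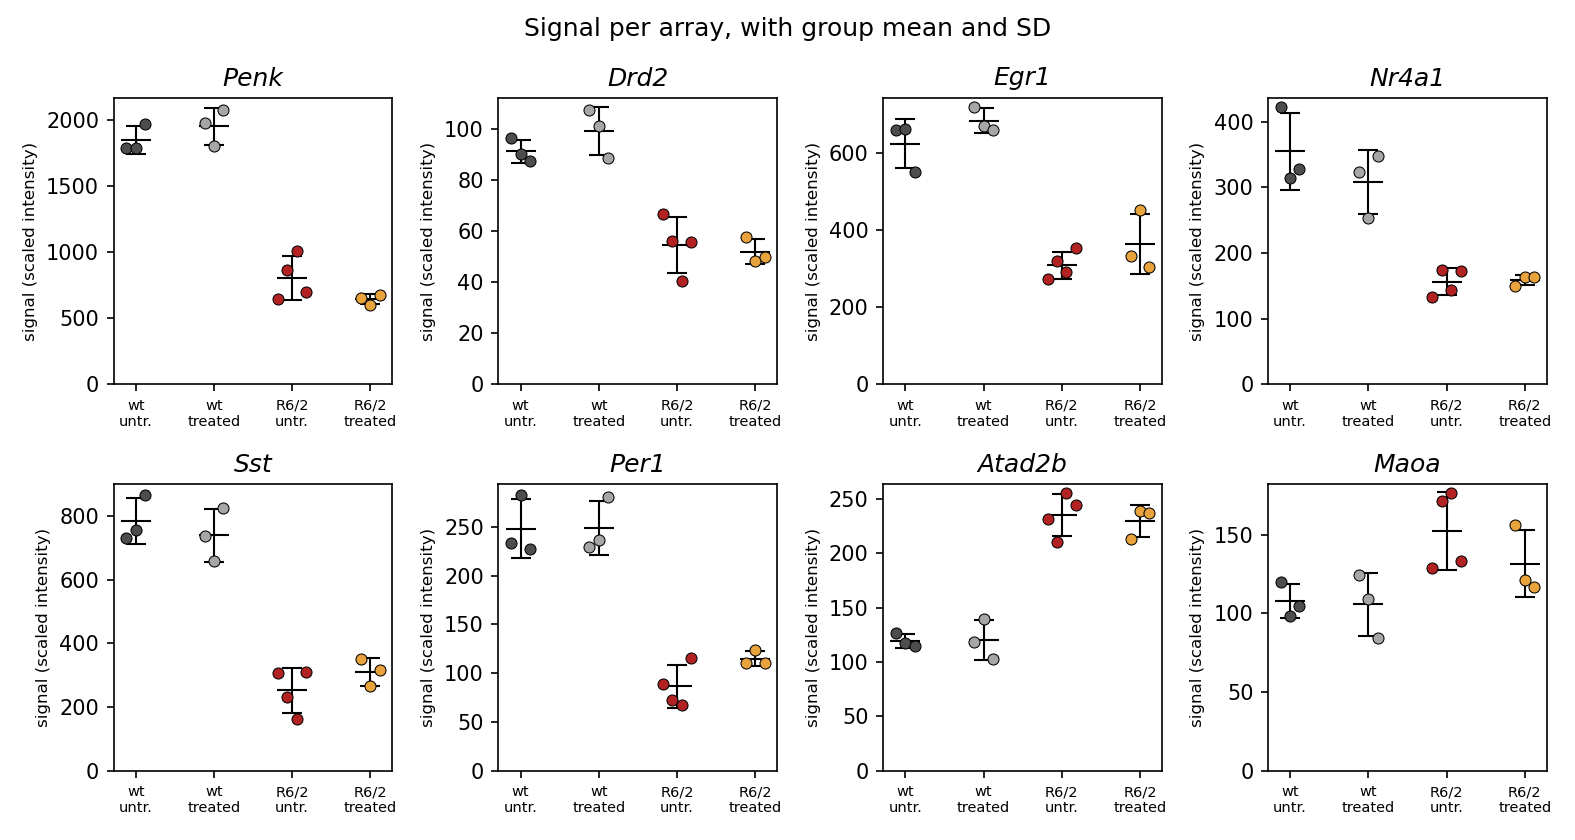
Signal (scaled intensity) of 8 genes in each of the 13 arrays, by group, with the group mean and SD as lines. Penk, Drd2, Egr1, Nr4a1, Sst and Per1 were lower and Atad2b higher in both R6/2 groups than in both wild type groups, and Maoa did not pass in either genotype comparison.

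The second question was which genotype differences were present under treatment. Striatal and early genes were lower in treated R6/2 than in treated wild type mice too. Penk changed by -1.60 ± 0.15 (SE, adjusted p = 0.000165), from 1952 ± 140 (SD, n = 3) to 644 ± 37.3 (SD, n = 3), Drd2 by -0.93 ± 0.18 and Hpca by -0.92 ± 0.13. Ptpn5, a striatal phosphatase gene, changed by -0.83 ± 0.15. In the striatal list 6 of 12 genes fell (adjusted p = 2.28e-21), and adjusted over the list alone 10 did. In the early gene list 6 of 17 fell (adjusted p = 2.46e-14), with Egr2 at -2.00 ± 0.21, Egr1 at -0.93 ± 0.15 and Dusp1 at -0.95 ± 0.16.

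The clock genes Dbp (-1.54 ± 0.22), Bhlhe40 (-1.32 ± 0.15) and Per1 (-1.11 ± 0.18) fell (adjusted p of the list = 0.000699). So did the neuropeptides Sst (-1.26 ± 0.21) and Cck (-0.74 ± 0.14), whose list had 16 of 17 estimates below 0 (adjusted p = 5.14e-13). Sgk1 fell by 0.77, and Wfs1, Gabrd, Gad1, which makes GABA, and the kinase gene Prkcb passed as falls in their lists. All 14 sterol synthesis genes had negative estimates and none passed singly (adjusted p of the list = 1.44e-07), with Fdps at -0.70 ± 0.17. The creatine list was lower (adjusted p = 0.00298), again with no gene past the threshold and with Ckmt1 at -0.56 ± 0.16. The myelin, astrocyte and glutamate and GABA lists passed, and each had an adjusted p of 0.0794 with an estimated correlation. The calcium, cortex and glucocorticoid lists also passed, with either correlation. The pan-neuronal list was not among the lists that passed. Its gene Syp read 264.8 to 311.1 in treated wild type and 320 to 339 in treated R6/2 mice, opposite to untreated mice. Syn2 and Atp2b2 overlapped between the treated genotypes, while Stx1a stayed lower in R6/2 mice (408.3 to 481 and 302.2 to 360.8). Higher in treated R6/2 mice were Tyms-ps (1.39 ± 0.23), Atad2b, which encodes a bromodomain protein (0.95 ± 0.14), the corepressor gene Sin3b (0.82 ± 0.13, and 0.03 on its other probe set), Polr2a (0.75 ± 0.16), the interferon-induced gene Ifitm3 (0.71 ± 0.13) and the transcription factor gene Nfya (0.65 ± 0.13).

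Of 7453 probe sets 59 passed, 6 higher and 53 lower. Of all 7453, 1252 (16.8%) had no overlap between the groups, against 10% by chance. This share does not set genotype apart, as the treatment comparisons, with 0 calls, also exceeded chance. They had 1622 (21.8%) against 10% in wild type mice and 789 (10.6%) against 5.71% in R6/2 mice. Of these 59, 47 also passed in untreated mice in the same direction, 3 higher where 0.33 would be expected by chance and 44 lower where 3.40 would be. These chance values take the 2 sets of calls as independent. Both comparisons use the same estimate of the spread per probe set, so the chance values may be too low. Of the 887 called in untreated mice, 669 (75.4%) had the same sign in treated mice, and across all probe sets, which are not independent, the 2 genotype effects correlated at r = 0.25 (rho = 0.198). The count of 59 was 20, 31, 33 and 35 without R6/2 treated array 1, wild type treated arrays 1 and 3 and R6/2 treated array 3, 95 without untreated R6/2 array 3, and 208 with array weights.

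**Figure D3:**
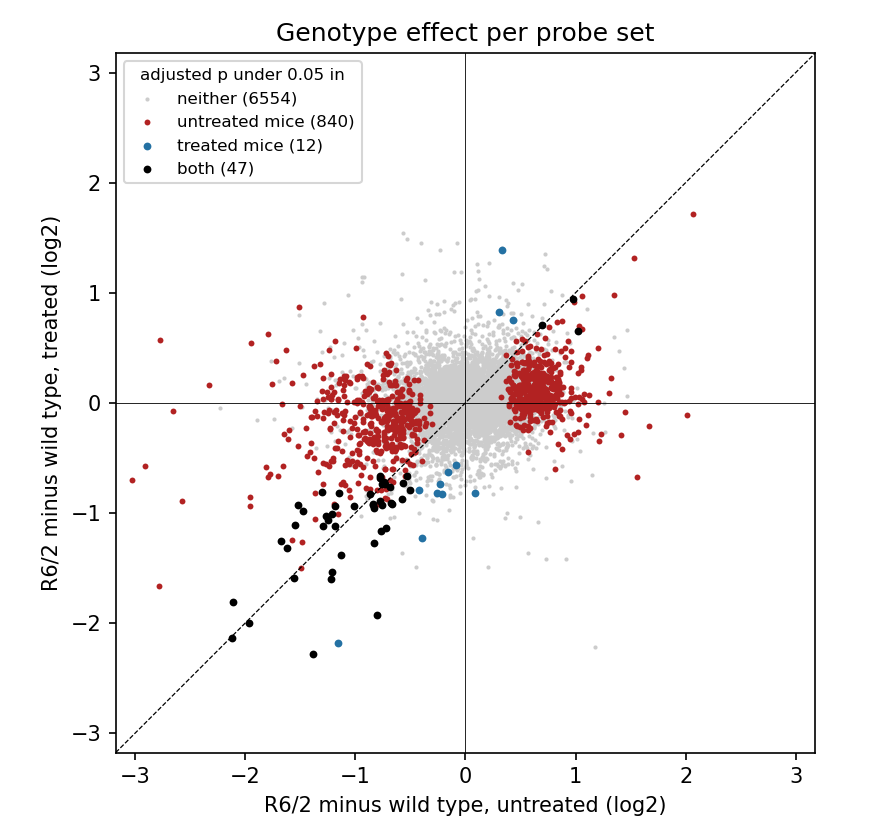
Genotype effect (R6/2 minus wild type, log2) of each of the 7453 probe sets in untreated (horizontal) and treated (vertical) mice, coloured by the comparison in which the adjusted p was under 0.05. The dashed line marks equal effects, and 47 probe sets passed in both.

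Averaged over both treatment arms, 493 probe sets separated the genotypes, 192 higher and 301 lower in R6/2 mice, including 5 and 41 at least 2-fold. Egr2 (-1.98 ± 0.14), Bhlhe40 (-1.47 ± 0.10) and Penk (-1.41 ± 0.10) shared the smallest adjusted p of 1.85e-06. The striatal list had 8 of 12 genes lower, among them Rasgrp2 (-1.16 ± 0.15), and the neuropeptide list 8 of 17, among them Npy (-0.84 ± 0.14). The myelin list had 7 of 13 lower (adjusted p = 0.0481 with an estimated correlation), with Mal at -0.67 ± 0.12 and Car2 at -0.59 ± 0.13. Higher were the class I histocompatibility gene H2-K2 (1.89 ± 0.46), the interferon-induced gene Ifit3 (1.01 ± 0.16), Lgals3bp (0.95 ± 0.18), the cholesterol transporter gene Abca1 (0.87 ± 0.13) and the replication gene Mcm5 (1.03 ± 0.21). H2-K2 was uneven among R6/2 arrays: untreated array 3 (27.4) and treated array 3 (19.1) read under wild type untreated array 3 (39.2). The proteasome list was the only 1 of 14 passing lists that was higher, with 1 gene past the threshold, Psme1 (0.42 ± 0.11), and it did not pass with an estimated correlation (adjusted p = 0.26). The count was 233 with untreated R6/2 array 1 alone, 423 without untreated R6/2 arrays 2 and 3, and 932 with array weights. It was 263 and 294 without wild type untreated arrays 2 and 3, 306 and 323 without wild type treated arrays 2 and 3, and 279 and 286 without R6/2 treated arrays 1 and 3.

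The third question was what treatment changed in R6/2 brain. No probe set passed in limma (smallest adjusted p = 0.246), while 1262 had an unadjusted p under 0.05 where 373 would be expected by chance. The smallest p-values among rises belonged to Psmb2, a proteasome subunit (0.64 ± 0.13), Cdk9, a transcription kinase (0.72 ± 0.15), Lmo1 (0.70 ± 0.15), Psap (0.58 ± 0.13) and angiotensinogen (Agt, 0.87 ± 0.20). Among falls they belonged to Rnf149 (-0.84 ± 0.16), Strbp (-0.77 ± 0.17), Tmeff2 (-0.81 ± 0.17), Pdxdc1 (-1.84 ± 0.42, with its other probe sets at -1.38 and 1.96) and Timp3 (-0.75 ± 0.17). The targets of the drugs did not pass. Ache was 214 ± 64.4 (SD, n = 4) untreated and 302 ± 24.8 (SD, n = 3) treated, a log2 change of 0.54 ± 0.20 (SE, adjusted p = 0.252), and Maoa was at -0.21 ± 0.17 (adjusted p = 0.516). Maob had no probe set annotated to it alone, and Bche lay below the filter. Ckb was at 0.66 ± 0.21 (adjusted p = 0.247), and Slc6a8, the creatine transporter, at -0.37 ± 0.16 (adjusted p = 0.272).

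Of the gene lists, the early genes (15 of 17 estimates positive, adjusted p = 0.049) and the 3 cholinergic genes (adjusted p = 0.049) were higher and the chaperones and oxidative phosphorylation genes (33 of 44 estimates negative) lower, each at an adjusted p of 0.0407. None passed with an estimated correlation (adjusted p = 0.586 each). The estimates included Nptx2 (0.61 ± 0.20) and Homer1 (1.00 ± 0.38, but 0.54 without untreated R6/2 array 3) among early genes, Chrm1 (0.73 ± 0.25) among cholinergic ones, Dnaja1 (-0.55 ± 0.19) among chaperones and Cox7b (-0.58 ± 0.15) among respiratory chain genes. Without untreated R6/2 arrays 2 and 3, Homer1 was at 0.43, Chrm1 at 0.20, Dnaja1 at -0.26 and Cox7b at -0.31, and of these 4 lists only the early genes passed (adjusted p = 0.000392). Ache was then at 0.16, Ckb at 0.30 and Strbp at -0.51. Without untreated R6/2 array 1 the count of probe sets was 116, 66 higher and 50 lower, and the early gene list did not pass (adjusted p = 0.289).

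**Figure D4:**
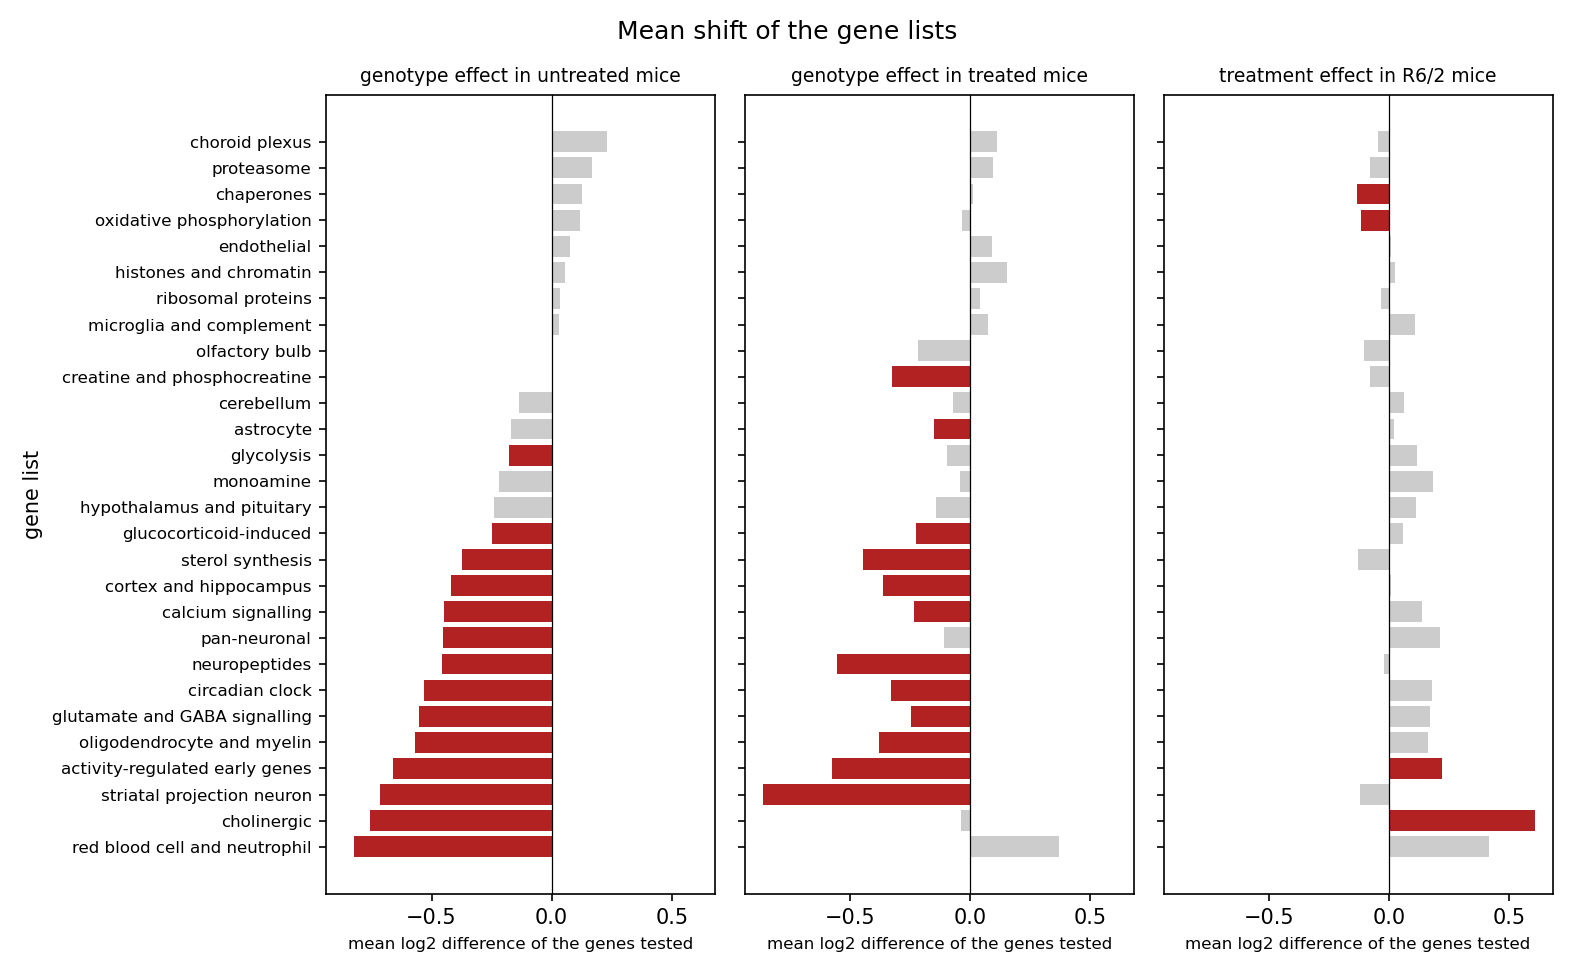
Mean log2 difference of the kept genes of each of the 28 lists in both genotype comparisons and in the treatment comparison of R6/2 mice. Red bars had an adjusted p under 0.05 by camera at the preset correlation of 0.01: 14, 12 and 4 lists.

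In wild type mice no probe set passed for treatment either in limma (smallest adjusted p = 0.0522), and 769 had an unadjusted p under 0.05. The smallest p-values were those of Snai2 (1.09 ± 0.16), Tex2 (1.58 ± 0.25) and the guanylate-binding protein gene Gbp7 (1.42 ± 0.23) among rises. Among falls they were those of Thrb, a thyroid hormone receptor (-1.93 ± 0.36), and the sodium channel gene Scn8a (-0.71 ± 0.16). Ache (-0.01 ± 0.22), Maoa (-0.04 ± 0.18) and Ckb (0.35 ± 0.22) did not pass, and no list passed. With array weights 120 probe sets passed, 76 higher and 44 lower. Treatment effects in R6/2 and in wild type mice did not run together across probe sets (r = -0.05).

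Averaged over the genotypes, treatment again gave 0 probe sets in limma (smallest adjusted p = 0.125, with 936 at an unadjusted p under 0.05). Psap (0.52 ± 0.09, with its other probe sets at -0.02 and -0.07), Pfn1, which encodes the actin-binding protein profilin (1.79 ± 0.32), Myef2 (-0.50 ± 0.09) and the fatty acid oxidation gene Eci2 (-0.52 ± 0.09) each had an adjusted p of 0.125. The early genes were the 1 list that passed (adjusted p = 0.0193, and adjusted p = 0.341 with an estimated correlation), with 14 of 17 estimates positive and Fosb at 0.41 ± 0.12. The count was 43 without untreated R6/2 array 1 and 17 with array weights.

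The last question was whether treatment acted differently in the 2 genotypes and moved R6/2 expression towards wild type. The interaction gave 0 probe sets in limma (smallest adjusted p = 0.305, with 1003 at an unadjusted p under 0.05). The smallest p-values were those of Syp (1.52 ± 0.31), Nfyb (1.04 ± 0.21), Mef2c (1.18 ± 0.24, and 0.36 to 0.95 on its 3 other probe sets), Akirin1 (-1.71 ± 0.37) and Snai2 (-1.01 ± 0.22). These estimates do not belong to R6/2 mice alone. Syp went from 442.5 to 572.8 down to 264.8 to 311.1 in wild type mice, and from 119.7 to 273.8 up to 320 to 339 in R6/2 mice. Nfyb also fell in wild type mice. Snai2 rose in wild type mice (30.1 to 35.2 and 68.5 to 74.2), while its R6/2 groups overlapped. The pan-neuronal and the red blood cell lists had positive interactions, each at an adjusted p of 0.0273, and each at an adjusted p of 0.636 with an estimated correlation.

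Of the 887 probe sets called for genotype in untreated mice, 804 (90.6%) had a treatment effect of opposite sign in R6/2 mice. Simulations without any effect gave 81.2% on average (78.1 to 84.6), because the same untreated R6/2 arrays stand in both differences. Across all probe sets the genotype and treatment effects correlated at r = -0.647, against -0.459 to -0.396 in the simulations. With separate untreated R6/2 arrays for each difference the share was 69.8% to 84.6% over the 6 splits, mean 77.0%, against 49.6% on average (37.2 to 56.6) in simulations of those splits without any effect. All these simulations drew noise independently for each probe set and with the same spread in every group. The real arrays share variation across probe sets and the untreated R6/2 group varied most, so chance can range wider than the simulations show. A displacement of the whole untreated R6/2 group would also raise the share with separate arrays just as treatment would. In the striatal list, whose 12 genotype estimates were all negative, 8 of 12 treatment estimates in R6/2 mice were negative too, and the mean signal of Penk was 804 untreated and 644 treated. For probe sets called in untreated mice the genotype effect in treated mice was 0.204 of that in untreated mice (median), and for those called in treated mice the effect in untreated mice was 0.891 of that in treated mice. The first ratio was 0.532 without untreated R6/2 arrays 2 and 3, and selection alone pulls both below 1.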

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

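The tests of explanations for the 3 patterns below were chosen only after the results were seen.

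In the untreated R6/2 group, the 1 group with enough arrays for the check, 179 measures were examined for a single array far from the rest, and 5 genes had one. About 5% would by chance, so 5 of 179 is no excess. For genes the gap to the nearest array over the whole range was taken on log2 values, while the readings given here are signals. It was 0.886 for the gap junction gene Gjb1, where array 2 read 34.9 and the others 18.2 to 19.6. It was 0.852 for the myelin gene Mag, where array 3 read 109.8 against 192.8 or more. It was 0.912 for Myef2 (array 4 at 147.7 against 168 or more), 0.834 for Myh7 (array 1 at 7.2 against 25.3 or more) and 0.87 for Psap (array 1 at 126.4 against 106.4 or less). The treatment effect differed between the genotypes for the pan-neuronal list and for the red blood cell and neutrophil list, each at an adjusted p of 0.0273 for the interaction. Neither list passed with an estimated correlation (adjusted p = 0.636 each).

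The genotype effect called 15.0 times as many probe sets in untreated as in treated mice. Treatment moving the changes back is 1 candidate explanation. With separate untreated R6/2 arrays for the 2 effects the share moved back was 77.0% on average, above the 37.2% to 56.6% of simulations without effect. Those simulations drew each probe set independently, so chance can range wider than they show. A displacement of the whole untreated R6/2 group would also give the same, so this explanation stays open. Untreated R6/2 arrays 2 and 3 may carry much of the excess: without them the ratio was 1.37, and without any other pair of untreated R6/2 arrays it was 4.08 to 21.4. Fewer arrays also lower the power in untreated mice. The treated count went from 59 to 119 without arrays 2 and 3 and to 58 to 107 without the other pairs. No untreated R6/2 array stands in the treated comparison, so its count can change only through the shared estimate of the spread. The ratio therefore depends on that estimate too. The untreated wild type arrays were not tested as a source of the excess. Leaving out any 1 of them also lowered the untreated count. On the second principal component they scored 10.3 to 17.8, against -3.01 to -0.409 in treated wild type mice. A displacement of the untreated wild type group thus stays open. RNA or array quality cannot be told apart from these explanations, since the control rows of 3 of the 4 untreated R6/2 arrays are multiples of another array's and measure nothing about them.

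Of the 35 splits of the 7 R6/2 arrays, the one that set untreated arrays 2 to 4 against array 1 and the treated arrays called 358 probe sets, where the labelled split called 0, which points to a structure of the samples. Those 3 arrays are exactly the 3 with copied control rows, so whatever was done to them may set them apart, though what it did to the gene probe sets is not known. On the first principal component, however, array 4 (2.83) lay with array 1 (4.09) and not with arrays 2 and 3 (25.4 and 45.7). A treated sample under the label of array 1 could give this as well, and its deviation from the other untreated arrays would then follow the treatment effect in wild type mice. The correlation was 0.0546 for array 1, and -0.125, 0.178 and -0.174 for arrays 2, 3 and 4, so array 3 followed that effect more closely. Treated R6/2 arrays did not follow it either (r = -0.05), so the test decides nothing. A batch that array 1 shares with the treated arrays stays open too, as 0 other arrays carry its label number and the labels name no batch.

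The control rows of untreated R6/2 arrays 2, 3 and 4 stood at 1.2 times those of R6/2 treated array 1, R6/2 treated array 3 and untreated R6/2 array 1. The same sample deposited under another name is argued against by the gene probe sets: at most 0.716% of them stood at that ratio in these pairs, within the 0.338% to 1.08% of the 153 other ordered pairs. Control rows written in after the arrays were scaled may explain it, since all 3 arrays had trimmed means of 100.074 to 100.128, outside the 100.047 to 100.053 of the other 10. No biological explanation was tested for control rows. What else was done to these 3 arrays is not known, which is why each genotype count is also given without them.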

How the results depend on the processing

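The alternatives that left out untreated R6/2 arrays 2 and 3, or 2 to 4, were chosen after seeing the data. The named genes and gene lists that passed kept their direction under every alternative, as is expected of results selected on largely the same arrays. Over named genes and alternatives, 7262 values kept their side of the threshold and direction, 493 no longer passed, 161 newly passed and 59 changed sign, all of these in genes that had not passed. Where the cause is not given by fewer arrays or probe sets, or by the shared estimate of the spread, the cause was not tested. Values under 3.1 were set to 3.1, which can narrow changes in dim genes, but only 0.00206% of the values of kept probe sets lay at or below it. No paired analysis was possible because the labels pair no samples.

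Probe sets called for the genotype effect in untreated mice (887) numbered 512 without the filter, 243 in a fit of only the groups compared, 163 without untreated R6/2 arrays 2 and 3 and 73 without arrays 2 to 4, where the lone array is assumed to vary like the other groups. Single arrays left out gave 157 to 1308. In treated mice (59) array weights gave 208, leaving out untreated R6/2 arrays 2 and 3 gave 119 and arrays 2 to 4 gave 113, and single arrays left out gave 20 to 95. Over both treatments (493) array weights gave 932, untreated R6/2 arrays 2 to 4 left out gave 233, and single arrays left out gave 263 to 704. The treatment effect in R6/2 mice (0) was 1 without the filter, 1 without untreated R6/2 arrays 2 and 3, 2 without arrays 2 to 4, and 0 to 116 with single arrays left out, the 116 being without untreated R6/2 array 1. In wild type mice (0) it was 2 without the filter, 1 without the intensity trend, 3 with robust variances, 120 with array weights, 9 with only the groups compared, 8 without untreated R6/2 arrays 2 and 3 and 8 without arrays 2 to 4, and 0 to 6 with single arrays left out. Over both genotypes (0) it was 17 with array weights, 1 without untreated R6/2 arrays 2 to 4 and 0 to 43 with single arrays left out. The interaction (0) was 1 without untreated R6/2 arrays 2 to 4.

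Of the gene list counts, that of the genotype effect in untreated mice (14) was 7 with an estimated correlation. That of the treatment effect in R6/2 mice (4) was 0 with quantile normalization, 1 without the filter, 1 without untreated R6/2 arrays 2 and 3, 0 with an estimated correlation, 0 with fry and 0 to 7 with single arrays left out. In wild type mice (0) single arrays left out gave 0 to 1. The interaction (2) gave 0 without the filter, 1 without untreated R6/2 arrays 2 and 3, 1 without arrays 2 to 4, 0 with an estimated correlation, 0 with fry and 0 to 5 with single arrays left out. The treatment effect over both genotypes (1) gave 0 with an estimated correlation, 0 with fry and 0 to 1 with single arrays left out. The list counts of the genotype effect in treated mice (12) and over both treatments (14) stayed within 9 to 15 and 10 to 17.

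The share moved back by treatment (90.6%) was 85.9% without the filter, 86.0% with array weights, 73.6% without untreated R6/2 arrays 2 and 3, 83.6% without arrays 2 to 4, 87.0% for the 100 probe sets with the smallest p and 85.2% to 94.7% with single arrays left out. With untreated R6/2 arrays 1 and 2, 1 and 3, 1 and 4, 2 and 3, 2 and 4, and 3 and 4 used for the genotype effect alone, it was 84.6%, 70.5%, 72.1%, 69.8%, 80.4% and 84.4%. The genotype effect in treated over untreated mice (0.204) was 0.273 without the filter, 0.532 without untreated R6/2 arrays 2 and 3, 0.473 without arrays 2 to 4 and 0.138 to 0.358 with single arrays left out. For probe sets selected in treated mice (0.891) it was 0.650 with array weights, 0.798 without untreated R6/2 arrays 2 and 3 and 0.730 to 1.02 with single arrays left out.

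For the genotype effect in untreated mice, Camp was at -0.029 with cyclic loess and -0.129 to 0.141 with single arrays left out. Without untreated R6/2 arrays 2 and 3 Gatm was at -0.033 and Bdnf at -0.272. Without arrays 2 to 4 Bdnf was at -0.251, and with single arrays left out it was at -0.007 to 0.269. For the treatment effect in R6/2 mice, Ckmt1 was at 0.047 and Gatm at 0.092 without untreated R6/2 arrays 2 and 3. Without arrays 2 to 4 Ckmt1 was at 0.284, Gatm at 0.042, Maoa at 0.015 and Xist at -0.417. Gamt ranged over -0.117 to 0.086 and Xist over -0.151 to 0.166 with single arrays left out, and Xist was at -0.007 with cyclic loess. For the treatment effect in wild type mice, Ache was at 0.018 with quantile normalization, 0.005 with cyclic loess and 0.022 with array weights, and Maoa at 0.020 with array weights. With single arrays left out Ache ranged over -0.103 to 0.167, Ckmt1 over -0.019 to 0.180 and Maoa over -0.162 to 0.116. For the genotype effect in treated mice, array weights put Gamt at 0.032 and Xist at 0.104. Single arrays left out gave -0.051 to 0.219 for Ache, -0.105 to 0.098 for Gamt, -0.105 to 0.106 for Htt and -0.182 to 0.134 for Xist. For the interaction, Camp was at -0.036 with array weights, -0.080 without untreated R6/2 arrays 2 and 3 and -0.015 to 0.346 with single arrays left out. Ckb was at -0.053 and Maoa at 0.031 without untreated R6/2 arrays 2 and 3. Without arrays 2 to 4 Ckb was at -0.070, Maoa at 0.053, Ckmt1 at 0.185 and Slc6a8 at 0.089, and Slc6a8 ranged over -0.135 to 0.127 with single arrays left out. For the genotype effect over both treatments, Ache was at 0.041 without untreated R6/2 arrays 2 and 3 and at 0.058 without arrays 2 to 4, and Gatm ranged over -0.078 to 0.021 with single arrays left out. For the treatment effect over both genotypes, Ckmt1 ranged over -0.049 to 0.051.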

Other observations

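The tests by other splits of the arrays had their bounds recorded only after their counts had been seen.

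Lists that did not pass for the genotype effect in untreated mice covered protein folding and turnover, mitochondria, glia and vessels. Chaperones (21 of 29 estimates positive, adjusted p = 0.0562), the proteasome (24 of 33 positive, adjusted p = 0.0788) and oxidative phosphorylation (29 of 44 positive, adjusted p = 0.148) had higher means in R6/2 mice, with 3, 3 and 4 genes past the threshold as rises and 2, 2 and 0 as falls. Astrocyte genes had 3 of 13 lower (adjusted p = 0.0562) and monoamine genes 3 of 15 lower (adjusted p = 0.0696). Microglia and complement, endothelial, ribosomal protein and olfactory bulb lists each had an adjusted p of 0.875. The adjusted p was 0.314 for cerebellum, 0.326 for choroid plexus and for hypothalamus and pituitary, 0.439 for histones and chromatin and 0.851 for creatine genes.

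The haemoglobin genes Hba-a1 and Hbb-b2 did not pass in untreated mice (adjusted p = 0.0662 and 0.110). Hba-a1 read 1831 ± 701 (SD, n = 3) in wild type untreated, 1046 ± 332 (SD, n = 3) in wild type treated, 899 ± 311 (SD, n = 4) in R6/2 untreated and 1283 ± 539 (SD, n = 3) in R6/2 treated mice. Alas2, the first enzyme of haem synthesis in red cells, changed by -1.515 ± 0.405 (SE) in untreated R6/2 mice (adjusted p = 0.0302), and over the alternatives its adjusted p ranged from 0.0172 to 0.489.

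Every comparison was repeated with the arrays divided into other groups of the same sizes. In untreated mice 1 of 35 splits gave as many genotype calls, the real one with 887. The next split, with 875, moved only untreated R6/2 array 4 to the wild type side. Moving only array 1, 2 or 3 there gave 750, 1 and 0 calls. Among these splits the count stayed high only with arrays 2 and 3 both on the R6/2 side. For the gene lists (14) 2 of 35 splits gave as many, so by that share chance was not excluded. The other of these (15) is the split that moved only array 4, and splits with 2 R6/2 arrays on each side gave 0 to 2 lists. Over both treatments 1 of 100 splits gave as many genotype calls (493, highest other 317) and 3 of 100 as many lists (14, highest other 16). Both shares lie under 0.05. The 100 splits were the real one and a random draw of the others, so both shares are estimates. Chance is unlikely rather than excluded for the calls. For the lists the share rests on too few splits to be set apart from 0.05, so chance was not excluded. In treated mice the real split gave 59 calls and 12 lists, the highest of the others 0 and 8, and 10 splits are too few for a share under 0.05.

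Where the real count was 0, every split gives as many, so the splits test nothing. This holds for the calls for treatment in R6/2 mice (35 of 35, highest other 358), for the interaction (100 of 100, highest other 2) and for treatment over both genotypes (100 of 100, highest other 3). In wild type mice the real split gave 0 calls and 0 lists, the highest others were 1 and 2, and 10 splits are too few for a share under 0.05. For the gene lists 4 of 35 splits gave as many as the 4 for treatment in R6/2 mice (highest other 6), 20 of 100 as many as the 2 for the interaction (highest other 6) and 36 of 100 as many as the 1 over both genotypes (highest other 4), so chance was not excluded for these lists.

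In the labels, the number in the title equals that in the description for every array except R6/2 treated array 1, whose title gives 5185 and whose description gives 5270, the number of untreated R6/2 array 4.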
